A study of Mus musculus with 48 samples.

How the data were processed

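RNA was measured by sequencing in 48 mouse libraries. They come from 2 brain regions, the dorsal vagal complex (DVC, a hindbrain site that receives gut signals) and the mediobasal hypothalamus (MBH), and from 2 kinds of RNA. The first kind is total RNA from a small part of each clarified homogenate (input), and the second is RNA bound to ribosomes that were pulled down from the rest of the homogenate with an antibody against phosphorylated ribosomal protein S6 (IP), a mark that rises in active neurons. Male C57/Bl6 mice aged 9 weeks were fasted for 6 h and received an intraperitoneal injection of 10 µL per g of saline, AC3174 at 1 µg/kg, AC170222 at 2.5 µg/kg, or both drugs. The protocol also writes AC710222 at 2.5 or 10 µg/kg and exenatide at 1 µg/kg, so the dose behind these libraries is not certain. The series title speaks of a GLP-1 and CCK combination. The doses within the combination, the time from injection to dissection and the number of mice behind each sample are not given in the sources used here. The treatment field of the labels writes the second drug as AC710222 and the sample titles write it as AC170222, which is the name used here. Each of the 16 groups of region, RNA kind and treatment holds 3 libraries.

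The labels give cDNA amplification with a SMART-Seq v4 kit, and tagmentation-based libraries that keep no strand. Per the submitters' processing notes, TopHat2 2.0.11, HTSeq 0.6.1p1 and the GRCm38 build were used; the annotation, the parameters and the strand setting are not given in the sources used here. The deposited table holds raw read counts per gene, as made by the authors, for 38293 Ensembl genes in the 48 libraries. Its values are whole numbers. Symbols and positions were taken from GENCODE M21 on GRCm38, which matched 36345 of the identifiers; 8 identifiers shared a symbol with another and were kept apart by identifier. No pair of the 48 replicate pairs held a copied library, since the lowest chi-square per degree of freedom between replicates was 130.1.

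Total counts per library ranged from 21782798 to 191252522. No molecular identifiers were used, so amplified copies of a molecule are counted as separate reads, and floors and intervals cover counting error only. A group in which all libraries had 0 counts was taken at a floor of 3 counts over the group when a fold was computed, and such folds are given as "at least". Fitted log2 differences of genes with many libraries at 0 depend on the prior count of the fit and are no bounds. CPM values (counts scaled to library size) were computed on TMM-scaled library sizes, and values after ± are SD for CPM and SE for log2 differences.

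Genes were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, 2-sided) in R 4.3.3. P values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. The 24 libraries of a region were fitted together for IP versus input and for the change of the IP-to-input ratio with treatment. The 12 IP libraries and the 12 input libraries of a region were also fitted on their own for each drug versus saline. In the IP libraries the combination was also compared with each single drug, and the non-additivity of the combination was tested as its change minus the sum of the changes with both single drugs. The saline inputs of DVC and MBH were compared as a measure of regional identity. This gave 27 comparisons. The difference between the regions in the IP-versus-input contrast and in each IP drug contrast was tested as an interaction over all 48 libraries.

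Input and IP of the same number are taken here to come from the same homogenate, which the titles do not state outright. Deviations of the 2 libraries from their group means had a median r of 0.018 in DVC and 0.001 in MBH, with 0 of 12 samples over 0.1 in either region, so the counts leave the pairing open. The IP-versus-input and ratio comparisons were fitted without and with this sample as a block, and both counts are given. As a check, deviations from the group mean of log2(CPM + 2) were correlated across genes with a mean of at least 10 CPM. Libraries of the same number in different treatments had r of -0.126 to 0.221 in DVC IP, -0.061 to 0.169 in DVC input, 0.025 to 0.350 in MBH IP and -0.074 to 0.160 in MBH input. A threshold of r = 0.1 was passed by 3, 4, 14 and 3 of the 18 pairs of each kind. In MBH IP the median was 0.16 against -0.069 for other numbers, and 10 of 12 libraries correlated best with their own number in each treatment (1 of 12 in each other kind). The labels state no pairing across treatments and not every pair passed, so a block on the number is given only among the alternatives, and in MBH IP the spread shared within a number stays in the tests.

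The 36 gene lists were fixed before the data were examined. They cover cell types of the brain and its linings, neuron and neuropeptide classes, appetite receptors, activity-induced and stress-induced genes, regional transcription factors, and ribosomal, mitochondrial and nuclear-retained RNA. Lists with at least 3 members tested were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of each comparison, and again with the correlation estimated from each list. Counts of called members are given over all genes tested and adjusted over the list alone. No list was chosen on these samples. Genes are named by a rule also fixed before the data were examined: per comparison, up to 12 genes with the largest log2 difference in each direction, with an adjusted p under 0.05, a mean log2 CPM of at least 2, complete separation of the groups (12 of 12 samples in the same direction for IP versus input) and a symbol other than a predicted gene. Where no gene met it, the 3 genes with the smallest p are given as values. From each list the members with the smallest p are named, and Fos, Glp1r, Cckar and Cckbr are given, where tested, for IP versus input, for each drug versus saline in the IP and in the input, and for the regions.

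Plate column and index in the sample titles split the libraries into 3 sets. In MBH IP, indices repeat within sets 2 and 3, leaving those of combination 1 and 2 in doubt. Saline and AC170222 hold sets 1, 1 and 2, AC3174 and the combination 2, 3 and 3, so set and treatment are partly confounded. The alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors, no low-count filter, a covariate for the set, the blocks, and leaving out each sample in turn. Chosen after seeing the data were limma-voom with sample quality weights, a minimum mean of 10 CPM, and leaving out the 6 libraries with counts for under 12000 genes. List tests without each sample were also chosen then, and samples whose absence ended a call are named with the highest adjusted p. Other groupings of the samples were fitted likewise.

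Simulated counts were drawn from the means, dispersions and sizes of the real libraries, with 200 genes changed 2-, 4- or 16-fold. At most 5 unchanged genes were called in any of 9 comparisons. Regrouping drug and saline libraries gave up to 431, so 5 is no bound on false calls. At 16-fold, 71.2% of the planted genes were called in DVC IP versus input, and for the combination versus saline 86.4% in DVC input, 56.1% in MBH input, 7.6% in DVC IP and 0 of 66 in MBH IP. At 4-fold, the combination versus saline called 0 of 67 in either IP and can miss changes of that size. The single drugs were not simulated.

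Reads were not analysed here to check strand, and overlapping or near-identical genes can share counts. Among the genes named in the report, Hdgfl2 overlaps Plin4, Msh6 overlaps Fbxo11, Srrm2 overlaps Elob, Fam171a2 overlaps Grn, P2ry12 lies within Med12l and Lrrc17 overlaps Fbxl13. The haemoglobin genes, Fth1 and Ftl1 and the ribosomal protein genes have close copies or pseudogenes. Of the list members, Lhfpl3, Lhb, Slc18a3, Kiss1, Kcnq1ot1 and Hoxd4 were not analysed here, because their symbols matched no identifier of the table. Some genes that the naming rule or the lists would name are not reported here.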

Results

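The data are raw read counts per gene from 24 DVC and 24 MBH libraries, with 3 libraries in each of the 16 groups. Total counts were 102116189 to 191252522 in the 12 DVC IP libraries, 29492622 to 95079227 in the 12 DVC inputs, 21782798 to 73940674 in the 12 MBH IP libraries and 36542586 to 80084056 in the 12 MBH inputs. A count was found for 16569 to 18200 genes in DVC inputs and for 9925 to 16796 genes in DVC IP libraries, the deepest of the series. MBH inputs held counts for 12853 to 18657 genes and MBH IP libraries for 6285 to 15913. Of the 6 libraries with under 12000 genes, all were IP: AC3174 3 in DVC (9925 genes), and saline 3 (11434), AC3174 2 (11006), AC3174 3 (6285), AC170222 2 (11812) and AC170222 3 (10050) in MBH. Common biological variation in the edgeR fits was 1.60 in DVC IP, 0.92 in DVC input, 1.81 in MBH IP and 1.12 in MBH input.

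**Figure D1:**
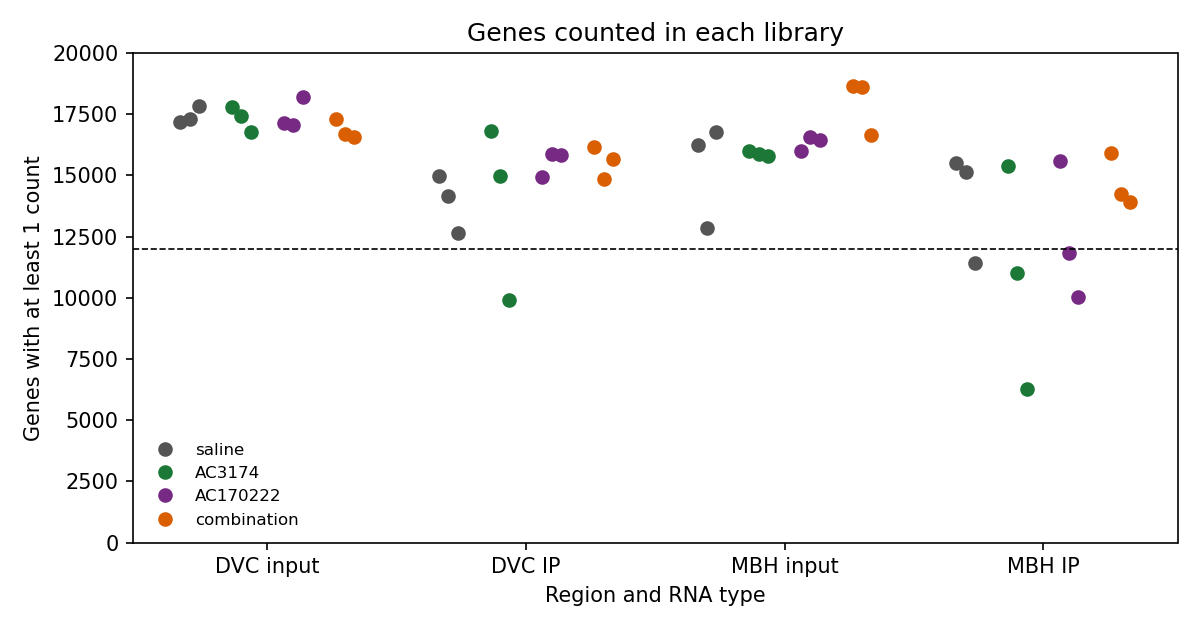
Genes with a count (vertical axis) in each of the 48 libraries, by region and RNA kind (horizontal axis) and treatment. DVC IP libraries hold 9925 to 16796 genes and DVC inputs 16569 to 18200.

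The first question is which transcripts were enriched on ribosomes carrying phosphorylated S6. In DVC the lists called higher in the IP were those of neuronal markers, respiratory chain, ribosomal protein, heat shock and red blood cell genes. The lists called lower included microglial, oligodendrocyte, mitochondrially encoded and nuclear-retained RNA, and with an estimated correlation none of these lists was called (lowest adjusted p = 0.0934). Chat, the enzyme that makes acetylcholine, was at 373 ± 198 CPM in the IP and 110 ± 40.3 CPM in the input (SD, n = 12 each; log2 1.79 ± 0.32, adjusted p = 0.000948). Pcp4l1 was at 1820 ± 568 against 486 ± 62.6 CPM (log2 1.89 ± 0.16, adjusted p = 2.42e-06). S100b, a calcium-binding protein of astrocytes and some neurons, was at 829 ± 184 against 286 ± 59.8 CPM (log2 1.54 ± 0.14, adjusted p = 6.47e-06). Kcna3, a potassium channel of immune cells and neurons, had 0 counts in 10 of 12 IP libraries and 13.1 ± 9.44 CPM in the inputs (fitted log2 -11.18 ± 1.29, adjusted p = 6.72e-05). P2ry12, a purine receptor of resting microglia, was at 1.41 ± 3.54 CPM with 9 of 12 IP libraries at 0, against 8.06 ± 3.79 CPM in the inputs (fitted log2 -8.76 ± 1.22, adjusted p = 0.00024). In GRCm38 coordinates, Chat lies on chromosome 14 from 32408203 to 32465989, Pcp4l1 on chromosome 1 from 171173262 to 171196268, Kcna3 on chromosome 3 from 107036169 to 107038070 and P2ry12 on chromosome 3 from 59216272 to 59262871.

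Of 18465 genes tested in DVC, edgeR called 1256 higher and 2520 lower in the IP, and 621 met the naming rule. Among the 12 named as higher were also Hdgfl2 at 478 ± 396 against 102 ± 17.5 CPM, Msh6 at 124 ± 76.4 against 31.3 ± 8.96 CPM, Lgals1 at 329 ± 147 against 95.1 ± 29.2 CPM and Atp5mpl at 820 ± 359 against 266 ± 51.8 CPM. Their adjusted p ranged from 1.71e-05 (Atp5mpl) to 0.000423 (Msh6). The other genes of that group were Cbwd1 (log2 1.89 ± 0.44), Cox7a1 (1.85 ± 0.41), Sh3bgr (1.80 ± 0.22), Vps33b (1.65 ± 0.33) and Vstm5 (1.54 ± 0.25). Among the genes named as lower was also Prrt3, at 0.808 ± 1.83 against 20.1 ± 5.69 CPM. Il13ra1, Zfp773, Lclat1, Sema3c, Tmem158, Tmem165, Itgav and Fam171a2 had fitted log2 values of -11.07 (Il13ra1) to -8.34 (Fam171a2).

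Neuronal markers were higher as a list: 5 of 14 members were called higher and 1 lower (9 and 1 adjusted over the list alone), with a median log2 of 0.44 (camera adjusted p = 3.99e-05, adjusted p = 0.202 with an estimated correlation). Snap25, a synaptic vesicle fusion protein, was at 11500 ± 2740 against 6240 ± 432 CPM, and the neurofilament genes Nefl (log2 1.49 ± 0.20) and Nefm (1.40 ± 0.23) and the growth-cone gene Stmn2 (0.76 ± 0.10) were called higher. The cholinergic motor list, which held Chat, was not called (median 0.47, adjusted p = 0.154). Isl1 (log2 1.91 ± 0.53, adjusted p = 0.0163) and Prph (0.86 ± 0.20, adjusted p = 0.00708) were higher and Ecel1 was lower (-2.49 ± 0.34, adjusted p = 9.56e-05). Nuclear-encoded respiratory chain mRNA was higher in 56 of 72 members and lower in 1 (59 and 3 over the list alone; median 0.80, adjusted p = 5.26e-43, 0.0934 with an estimated correlation), with Cox7b at 1110 ± 330 against 407 ± 64.6 CPM. Ribosomal protein mRNA was higher in 33 of 80 members and lower in 0 (46 and 0 over the list alone; median 0.50, adjusted p = 3.09e-20, 0.25 with an estimated correlation), as for Rpl41 (log2 1.07 ± 0.23) and Rpl4 (0.54 ± 0.11). Heat shock chaperones were higher in 3 of 8 members (4 over the list alone; median 0.81, adjusted p = 0.00345, 0.221 with an estimated correlation), namely Hsp90aa1, Hspa8 and Dnajb1. Haemoglobin mRNA, a marker of blood, was higher in 2 of 5 red blood cell genes (4 over the list alone; median 1.15, adjusted p = 0.00472, 0.221 with an estimated correlation), with Hbb-bs at 134 ± 104 against 49.0 ± 31.4 CPM.

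Microglial genes were lower in 8 of 12 members (8 over the list alone; median -5.37, or -4.39 with genes at 0 taken at their bound; adjusted p = 3.68e-06, 0.0934 with an estimated correlation). Csf1r, the receptor these cells need to survive, had 0 counts in 11 of 12 IP libraries and 13.7 ± 5.26 CPM in the inputs, and Cx3cr1 was at 1.47 ± 4.72 against 8.47 ± 5.45 CPM. Oligodendrocyte genes were lower in 4 of 12 members (6 over the list alone; median -1.51, adjusted p = 4.16e-05, 0.237 with an estimated correlation). Among them were the myelin genes Mbp, at 1080 ± 641 against 2810 ± 442 CPM, and Cnp (log2 -0.83 ± 0.13). Oligodendrocyte precursor genes were lower in 4 of 7 (5 over the list alone; median -4.60, -3.98 with bounds; adjusted p = 0.0256, 0.205 with an estimated correlation), Olig2 among them (log2 -5.55 ± 1.27). Pericyte and smooth muscle genes were lower in 3 of 8 (5 over the list alone; median -3.82, -3.48 with bounds; adjusted p = 0.0259, 0.205 with an estimated correlation and 0.0941 with the sample as a block), Myh11 and Acta2 among them. The astrocyte list was not called (median -0.55, test direction up, adjusted p = 0.516), with Gfap, the intermediate filament of astrocytes, higher (log2 0.64 ± 0.22, adjusted p = 0.0499) like S100b. The endothelial list was not called either (4 of 10 members lower, median -4.57, adjusted p = 0.117), with Cdh5 (log2 -5.81 ± 1.18) and Cldn5 (-5.09 ± 1.65) among the lower genes.

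The 13 mitochondrially encoded mRNAs were all called lower in the IP, over all genes and over the list alone (median -4.67, adjusted p = 3.27e-13, 0.205 with an estimated correlation), with mt-Co1 at 86.7 ± 124 against 1630 ± 1210 CPM. Nuclear-retained RNA was lower in 3 of 5 members (4 over the list alone; median -1.74, adjusted p = 0.00316, 0.254 with an estimated correlation), with Malat1 at 524 ± 461 against 3550 ± 822 CPM. Lower as well were markers of DVC neurons (6 of 11 called, 7 over the list alone; median -5.31, -4.06 with bounds; adjusted p = 0.000816, 0.221 with an estimated correlation). Gcg, which encodes the GLP-1 precursor, was at 1.72 ± 4.73 against 7.70 ± 5.32 CPM, with 9 of 12 IP libraries at 0. Gut peptide and appetite receptors were lower in 9 of 25 members (11 over the list alone; median -3.29, -2.89 with bounds; adjusted p = 0.0019, 0.205 with an estimated correlation), Insr (log2 -5.69 ± 1.33) and Drd2 (-6.34 ± 1.47) among them. Cholesterol synthesis genes were lower in 3 of 16 (3 over the list alone; median -1.37, adjusted p = 0.0202, 0.441 with an estimated correlation), among them Cyp51 and Insig1. The immediate early list was not called (1 of 23 higher, 5 lower; median -0.86, adjusted p = 0.291): Klf2 and Npas4 were lower and Gadd45b higher (1.03 ± 0.27). Nr4a1 (fitted log2 -2.91 ± 0.43) had 0 counts in saline IP but no lower mean CPM than input with any drug. Not called were Fos, at 53.0 ± 34.0 against 31.1 ± 9.97 CPM (adjusted p = 0.671), Cckar (log2 -2.59 ± 1.63, 0.317) and Cckbr (-3.02 ± 1.32, 0.122). Glp1r was at 0.41 ± 0.845 against 1.36 ± 1.69 CPM (adjusted p = 1).

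With the sample shared by input and IP as a block, 1401 genes were called in DVC in place of 3776. Of the 9753 genes common in DVC inputs, 0.53% (AC3174 1) to 30.0% (AC3174 3) had no count in the IP of the same sample. Such loss was not separated from depletion in lists of rare RNA. Without the low-complexity library, 4196 genes were called. The oligodendrocyte precursor list lost its call without AC3174 3 (adjusted p of 0.086) and pericyte without AC3174 1 or combination 3 (up to 0.0584).

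In MBH the genes named as higher in the IP included Srrm2 and Msh6, and those named as lower included Fth1 and 5 mitochondrial RNAs. Srrm2, a scaffold of nuclear speckles, was at 1160 ± 532 CPM in the IP and 175 ± 65.3 CPM in the input (SD, n = 12 each; log2 2.76 ± 0.30, adjusted p = 0.000247). Msh6, a mismatch repair protein, was at 263 ± 197 against 31.0 ± 19.1 CPM (3.05 ± 0.50, adjusted p = 0.0111). Bod1l was at 513 ± 484 against 79.8 ± 35.3 CPM. The iron storage gene Fth1 was lower, at 1120 ± 440 against 2970 ± 542 CPM (log2 -1.41 ± 0.18, adjusted p = 0.000999), as were Ftl1 (-1.01 ± 0.22, adjusted p = 0.0427), Cirbp (-1 ± 0.17) and Lrrc17 (9.91 ± 13.8 against 106 ± 54.0 CPM). Srrm2 lies on chromosome 17 from 23790532 to 23824741 and Fth1 on chromosome 19 from 9980598 to 9985098.

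Of 17461 genes tested in MBH, edgeR called 28 higher and 51 lower in the IP, and 33 met the naming rule. The other named genes on the higher side were Zc3h13 (log2 1.61 ± 0.23), Thrap3 (1.40 ± 0.25), Prpf4b (1.31 ± 0.25) and Srrt (0.93 ± 0.19). To these come Map7d2 (1.79 ± 0.39), Bcas1 (1.79 ± 0.36), Pnmal2 (1.06 ± 0.23) and Mpp1 (1.05 ± 0.21). On the lower side were the mitochondrial RNAs mt-Nd3 (-6.72 ± 1.25), mt-Rnr1 (-5.16 ± 1.03), mt-Nd2 (-4.56 ± 1.01), mt-Nd4 (-4.29 ± 0.94) and mt-Rnr2 (-3.58 ± 0.74). Ficd (fitted -9.21 ± 1.59, 10 of 12 IP libraries at 0), Nrsn1 (-1.53 ± 0.28) and Selenok (-1.29 ± 0.24) were lower too. Over the 16859 genes tested in both regions, 40 of the 79 called in MBH were called in the same direction in DVC (16 higher, 24 lower) and 6 in the opposite direction, against 9.1 in the same direction for independent lists.

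Mitochondrially encoded mRNA was lower as a list in MBH too (3 of 13 called, 13 over the list alone; median -3.82, adjusted p = 1.11e-23, 0.0782 with an estimated correlation). So was nuclear-retained RNA (1 of 5 called; median -0.99, adjusted p = 0.00263, 0.243 with an estimated correlation), with Malat1 at 480 ± 587 against 1910 ± 499 CPM. Red blood cell genes were higher (0 of 5 called, 3 over the list alone; median 1.41, adjusted p = 4.98e-07, 0.0782 with an estimated correlation), with Hbb-bs at 66.6 ± 38.8 against 26.1 ± 19.4 CPM. Immediate early genes had a median log2 of 0.58 with 16 of 24 members positive and 0 called (adjusted p = 0.0239, 0.53 with an estimated correlation and 0.0752 with the sample as a block). Junb had 0.94 ± 0.35, Fosb 3.15 ± 1.31 and Fos 1.13 ± 0.83, at 75.0 ± 52.2 against 32.0 ± 8.45 CPM (adjusted p = 0.828). Arcuate neuropeptide genes were lower (0 of 11 called, 1 over the list alone; median -0.95, adjusted p = 0.00331, 0.153 with an estimated correlation), with Npy at log2 -0.60 ± 0.31 and Nmu at -6.05 ± 1.65. Ribosomal protein mRNA was lower (0 of 78 called; median -0.41, adjusted p = 0.00443, 0.697 with an estimated correlation).

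Further lists lower in MBH with 0 called members were unfolded protein response genes (median -1.18, adjusted p = 0.0118, 0.321 with an estimated correlation), oligodendrocyte genes (-1.13, 0.0253, 0.53), microglial genes (-1.76, -1.22 with bounds, 0.0253, 0.52), gut peptide and appetite receptors (-1.33, 0.0253, 0.53) and cholesterol synthesis genes (-0.60, 0.0253, 0.53). The last 3 were no longer called with the sample as a block (adjusted p = 0.0752, 0.0579 and 0.0569). Cckar had a log2 of -1.54 ± 1.53 (adjusted p = 0.98), Cckbr of -5.18 ± 1.78 (0.201) and Glp1r of -4.75 ± 1.81 (0.274).

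**Figure D2:**
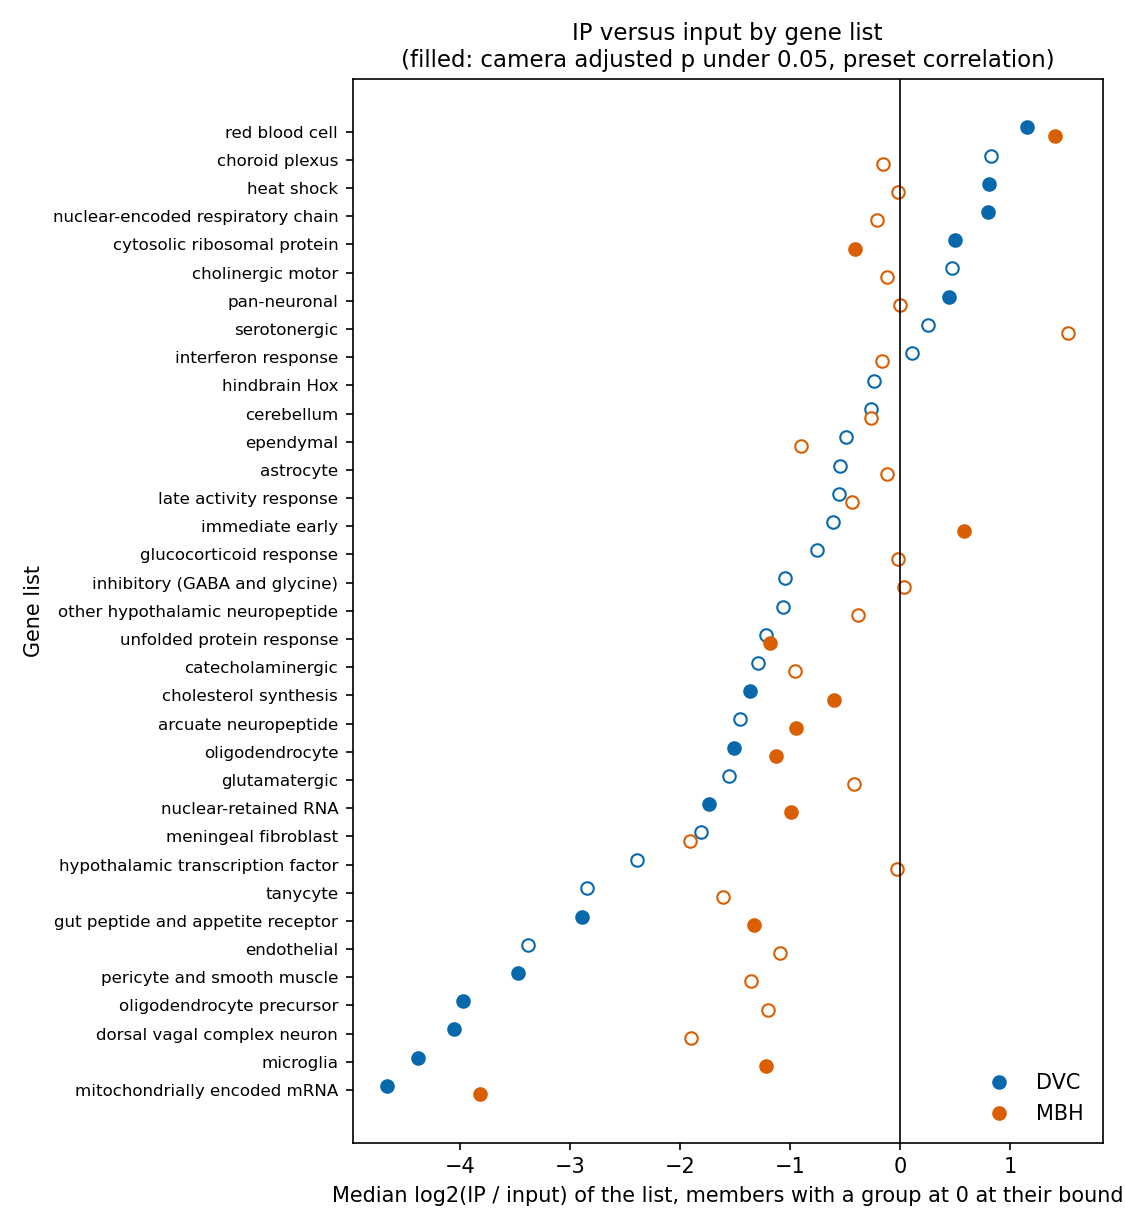
Median log2 difference between IP and input (horizontal axis) for the members of each gene list in DVC and MBH, with filled points for lists called by camera at the preset correlation. Mitochondrially encoded mRNA sits at -4.67 in DVC and -3.82 in MBH.

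Nuclear-retained RNA differed between samples in how far the IP lacked it, with a median log2 IP-to-input ratio from -5.37 (combination 2) to 0.17 (AC3174 3) in DVC and from -4.16 (AC3174 2) to 2.25 (AC170222 3) in MBH.

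**Figure D3:**
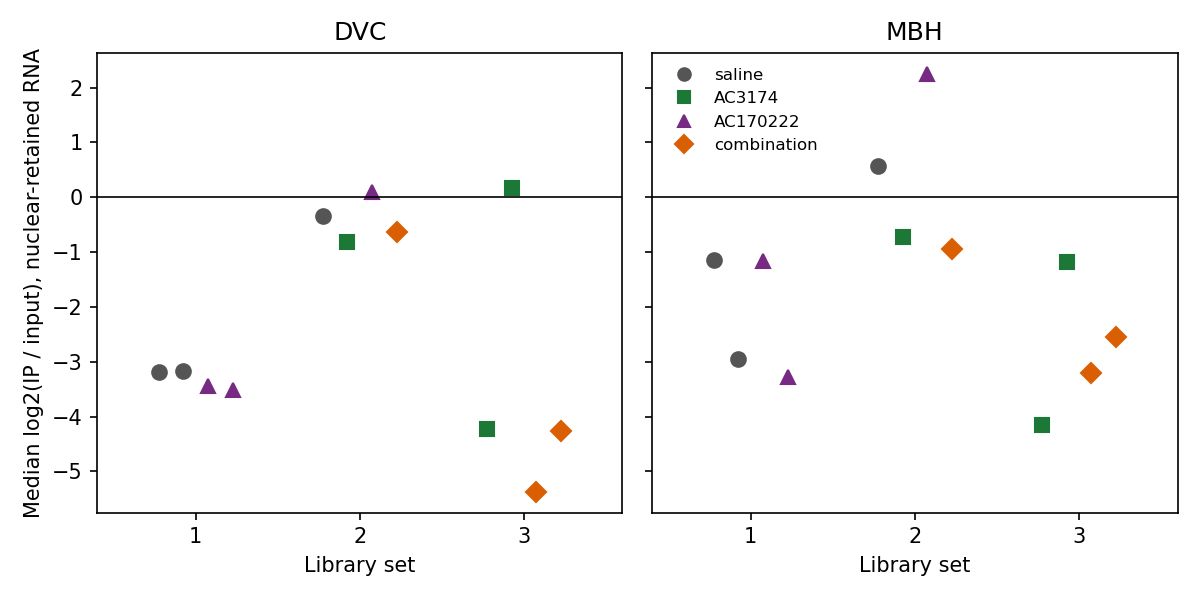
Median log2 ratio of IP to input over the nuclear-retained RNAs (vertical axis) in each sample, by library set (horizontal axis) and treatment. In DVC the 4 samples of set 2 lie between -0.82 and 0.09, the 4 of set 1 between -3.51 and -3.17 and the 4 of set 3 between -5.37 and 0.17.

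The MBH count moved with most single samples. With the sample as a block 3 genes were called, and without the 5 low-complexity libraries 363. Without 1 sample at a time, edgeR called 587 (AC3174 1), 30 (AC170222 3), 29 (saline 3), 20 (saline 2), 15 (AC3174 2), 11 (AC170222 2), 10 (saline 1), 10 (combination 1), 4 (combination 2) and 4 genes (combination 3). Among the MBH lists, the arcuate neuropeptide list lost its call without AC3174 1 (adjusted p of 0.0528), cholesterol synthesis without AC170222 3 or AC3174 1 or 3 (up to 0.104), ribosomal protein without AC170222 1, AC3174 1, combination 1 or saline 2 (up to 0.902), receptor without saline 2 (0.102), immediate early without AC170222 1 or 2, AC3174 1 or 2 or saline 2 (up to 0.18), microglial without any sample but saline 2 and combination 2 (up to 0.21) and oligodendrocyte without AC3174 1 or saline 2 (up to 0.0557).

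The next question is what each drug and the combination changed on these ribosomes in DVC. No gene passed the test in the IP libraries, where Nr4a1 and Mlh3 had the smallest p values. Nr4a1, a nuclear receptor gene induced early by neuronal activity, had 0 counts in all 3 saline IP libraries and was at 12.4 ± 6.55 CPM with AC3174, 20.9 ± 7.97 with AC170222 and 12.2 ± 6.42 with the combination (SD, n = 3). These values are at least 1790-fold, 3010-fold and 1760-fold over the floor of 3 counts (adjusted p = 0.337, 0.388 and 0.489 by edgeR). Mlh3, a mismatch repair gene, was at 0 in the same saline libraries and at 38.2 ± 27.8, 24.1 ± 13.0 and 32.9 ± 17.4 CPM (adjusted p = 0.26, 0.322 and 0.277). Fos was at 38.1 ± 37.7 CPM with saline, 31.5 ± 31.8 with AC3174, 86.9 ± 29.1 with AC170222 and 55.6 ± 18 with the combination, with log2 differences of -0.26 ± 2.19, 1.18 ± 2.22 and 0.58 ± 2.20 from saline. Cckar and Cckbr had 0 counts in all 3 DVC IP libraries of the combination and Glp1r in those of AC170222; in the IP of the other treatments Cckar stood at 3.43 to 10.2, Cckbr at 2.26 to 29.5 and Glp1r at 0.312 to 0.907 CPM. Nr4a1 lies on chromosome 15 from 101254269 to 101274795, Mlh3 on chromosome 12 from 85234520 to 85270599 and Fos on chromosome 12 from 85473890 to 85477273.

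Of 15815 genes, edgeR called 0 for AC3174, AC170222 and the combination versus saline, with 1041, 830 and 861 genes at an unadjusted p under 0.05; DESeq2 called 1144, 906 and 935, and limma-voom 3, 35 and 31. Among genes with the next smallest p, the lysosomal transporter gene Atp13a2 had a log2 of 8.81 ± 1.41 with AC3174, Cox5a -1.34 ± 0.24 with AC170222 and Csnk1a1 1.65 ± 0.32 with the combination. Immediate early genes were higher as a list with the combination (0 of 19 called, 1 over the list alone, 14 positive; median 0.78, adjusted p = 0.00924, 0.766 with an estimated correlation and 0.125 with the library set as a covariate). Jun was at a log2 of 2.45 ± 1.04 and Fosb at 3.34 ± 3.88 CPM against 0 in the 3 saline libraries. Ribosomal protein mRNA was lower with AC3174 (median -0.57, adjusted p = 7.41e-08), AC170222 (-0.44, 9.55e-10) and the combination (-0.72, 8.92e-20), and so was respiratory chain mRNA (-0.40, 5.11e-06; -0.31, 9.55e-10; -0.41, 6.54e-10). No list was called in these 3 comparisons at an estimated correlation (lowest adjusted p = 0.968, 0.894 and 0.766). With the combination, mitochondrially encoded mRNA (median -2.48, adjusted p = 6.37e-06) and nuclear-retained RNA (-1.62, 0.00223) were lower, and with AC170222 mitochondrially encoded mRNA (-0.20, 0.0187) and choroid plexus genes (-2.71, 0.0337). Saline 3 stood apart from saline 1 and 2: against the saline mean, the median log2 of nuclear-retained RNA was -0.83, -1.07 and 0.96 in the 3 libraries and that of mitochondrially encoded mRNA -2.83, -1.32 and 1.29. For AC3174 the ribosomal protein list lost its call without AC3174 1 or saline 3 (adjusted p up to 0.569) and respiratory chain without AC3174 1 (0.569). For AC170222 the choroid plexus list lost its call without AC170222 1 or 2 or saline 3 (adjusted p up to 0.975), ribosomal protein without AC170222 3 or saline 3 (up to 0.0901), mitochondrially encoded without AC170222 1 or 2 or saline 3 (up to 0.944) and respiratory chain without AC170222 3 (0.12). For the combination the immediate early list lost its call without saline 3 (adjusted p of 0.107), mitochondrially encoded without saline 3 (0.132) and nuclear-retained without saline 3 (0.132).

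Whether the combination differed from each drug alone, or from their sum, was tested directly in the DVC IP. Of 15815 genes edgeR called 0 for the combination versus AC3174 (397 at an unadjusted p under 0.05; 442 by DESeq2, 0 by limma-voom), 0 versus AC170222 (424; 387 and 35) and 0 for non-additivity (723; 883 and 5). Against AC170222 the smallest p values belonged to Wasl (log2 2.10 ± 0.42), Cox5a (1.21 ± 0.24) and Cyc1 (1.01 ± 0.22). Against AC3174 they belonged to Nnmt (12.3 ± 11.8 against 0.00209 ± 0.00362 CPM), Bcl2a1b (at least 65.7-fold) and Plek2 (10.6 ± 6.99 against 0.00209 ± 0.00362 CPM), each with an adjusted p of 1. For non-additivity, Mlh3 had a fitted log2 of -14.87 ± 1.97, Nr4a1 of -14.46 ± 2.15 and Naa16 of -15.04 ± 2.89 (adjusted p = 0.586, 0.729 and 0.968), all 3 with 0 counts in the saline IP libraries. Against AC3174, mitochondrially encoded mRNA (median -1.68, adjusted p = 0.000203), nuclear-retained RNA (-1.42, 0.0223) and ribosomal protein mRNA (-0.13, 0.0294) were lower with the combination, and against AC170222 ribosomal protein mRNA (-0.29, 0.0178). Respiratory chain mRNA was higher in the non-additivity contrast (0.35, 0.00086). The lowest adjusted p with an estimated correlation was 0.9, 0.987 and 0.951. Against AC3174 the ribosomal protein list lost its call without AC3174 2 or 3 or combination 1 or 3 (adjusted p up to 0.38), mitochondrially encoded without AC3174 3 (0.0796) and nuclear-retained without AC3174 1 or 3 or combination 2 or 3 (up to 0.812). Against AC170222 the ribosomal protein list lost its call without AC170222 1 or 2 or combination 1 or 3 (adjusted p up to 0.725). For non-additivity the respiratory chain list lost its call without AC170222 3, AC3174 1 or saline 3 (adjusted p up to 0.637).

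The change of the IP-to-input ratio asks whether a drug altered what the IP held beyond any change in the tissue. In DVC this ratio was higher for Nr4a1 with AC3174 (fitted log2 14.24 ± 1.51, adjusted p = 0.00035), AC170222 (14.04 ± 1.51, 0.00079) and the combination (13.32 ± 1.48, 0.000662). Its input stood at 12.6 ± 2.86 CPM with saline and 6.52 ± 4.28, 12.6 ± 6.60 and 12.1 ± 3.41 with the drugs. Mlh3 (14.23 ± 1.52, 13.07 ± 1.48 and 13.83 ± 1.5), Rfx7, Hgh1 and Lrp8os3 were also called with each drug, and Mlh3, Rfx7 and Hgh1 had 0 counts in every saline IP library. Against the floor of 3 counts, Rfx7 was at least 2930-fold, 1370-fold and 2070-fold higher in the IP, and Hgh1 at least 4920-fold, 434-fold and 1600-fold. Lrp8os3 was at 20.4 ± 25.8, 8.30 ± 4.57 and 6.42 ± 4.18 CPM in the IP against 0.00224 ± 0.00388 with saline. Further calls were Atp13a2 (log2 8.40 ± 1.18; 189 ± 127 CPM in the IP against 0.434 ± 0.237 with saline) and Bbc3 (10.5 ± 14.2 against 0.00315 ± 0.00545 CPM) for AC3174. For the combination they were Mtmr10 (at least 7660-fold in the IP) and Fam135a (61.2 ± 9.03 against 0.00224 ± 0.00388 CPM).

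**Figure D4:**
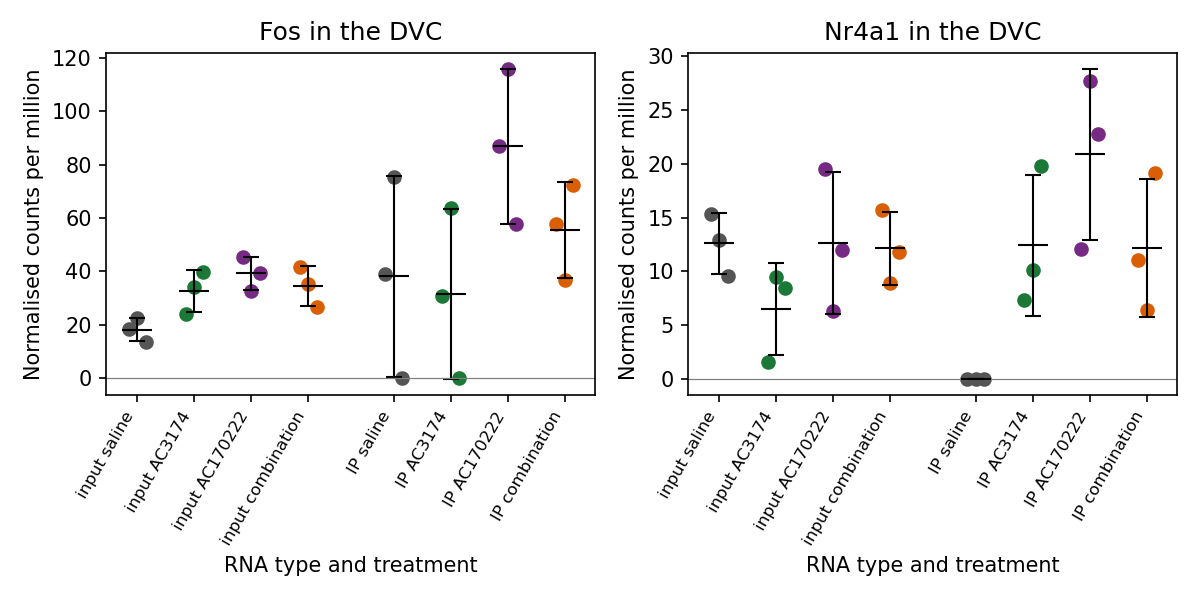
CPM of Fos and Nr4a1 (vertical axis) in each DVC input and IP library, by treatment, with the mean of 3 libraries and its SD. Fos in the saline inputs lies between 13.6 and 22.4 CPM, below the 9 drug inputs at 24.1 to 45.5 CPM.

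Of 18465 genes, edgeR called 7, 5 and 7 higher and 0 lower for the ratio with AC3174, AC170222 and the combination (1921, 1665 and 1764 at an unadjusted p under 0.05; 1919, 1649 and 1800 by DESeq2 and 0, 5 and 4 by limma-voom). With the sample as a block edgeR called 0 in each. Each pair of lists shared 5 genes, and independent lists would share 0.0019 to 0.0027. In 20 simulations without drug effects but with the shared saline samples 0 calls were shared, a value fixed by lists of at most 1 gene. Across genes, which are not independent replicates, log2 differences of the 3 pairs had r of 0.59, 0.59 and 0.60 (0.50, 0.49 and 0.50 simulated). Covariances were 11.31, 11.92 and 11.51 (6.32, 6.27 and 6.35). Regrouped AC3174 and saline libraries gave up to 241 calls, unlike simulated ones, so overlap, r and covariance are not separated from shared saline libraries. Ribosomal protein mRNA had a lower ratio with AC3174 (median -0.41, adjusted p = 0.00414), AC170222 (-0.37, with a mean of 0.01, 7.4e-05) and the combination (-0.70, 3.54e-13). At the estimated correlation no list was called for the ratio (lowest adjusted p = 0.958, 0.921 and 0.942). By sample, the median log2 ratio of ribosomal protein mRNA was 0.52, 0.56 and 1.46 in saline 1, 2 and 3, so that saline 3 stood apart. It ran from -0.51 to 1.30 with AC3174, -0.04 to 1.02 with AC170222 and -0.16 to 0.61 with the combination. Respiratory chain mRNA also had a lower ratio (-0.38, 0.000117; -0.22, 7.4e-05; -0.51, 7.61e-09), and so had mitochondrially encoded mRNA with the combination (-2.83, 5.4e-06).

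The ratio counts moved with single samples. Without saline 1, 2 or 3, edgeR called 45, 50 and 15 genes for AC3174, 38, 36 and 3 for AC170222, and 40, 42 and 4 for the combination. Without AC3174 1 or 3 it called 30 and 33 for that drug, without AC170222 1, 2 or 3 it called 3, 2 and 9, and without combination 1, 2 or 3 it called 3, 4 and 3. Without the low-complexity library the counts were 74, 61 and 74. Among the lists with AC3174 the ribosomal protein list lost its call without AC3174 1 or 2 or saline 3 (adjusted p up to 0.885) and respiratory chain without AC3174 1 (0.997). Among those with AC170222 the ribosomal protein list lost its call without AC170222 3 or saline 3 (adjusted p up to 0.67) and respiratory chain without AC170222 3 (0.691). With the combination the mitochondrially encoded list lost its call without saline 3 (adjusted p of 0.23).

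In the DVC input Fos was at 18.2 ± 4.42 CPM with saline, 32.5 ± 7.83 with AC3174, 39.2 ± 6.31 with AC170222 and 34.6 ± 7.41 with the combination (SD, n = 3). All 9 drug inputs lay above the 3 saline inputs. The log2 differences of 0.84 ± 0.29, 1.10 ± 0.30 and 0.93 ± 0.29 had unadjusted edgeR p values of 0.016, 0.0032 and 0.0089 and did not pass the correction over all genes (adjusted p = 0.993, 1 and 0.891). Ccn1, a matrix protein gene of the immediate early list, had 0 counts in the 3 saline inputs and 2.00 ± 0.771, 2.81 ± 0.952 and 4.64 ± 3.44 CPM with the drugs. These are at least 142-fold, 200-fold and 330-fold over the floor (adjusted p = 0.948, 0.772 and 0.273). Glp1r was at 0 in the 3 saline inputs and at 2.42 ± 2.51, 1.54 ± 0.934 and 1.5 ± 1.99 CPM (adjusted p = 0.993, 1 and 0.891). Cckar had log2 differences of 0.48, -1.73 and -0.61 and Cckbr of -0.42, 0.17 and 0.36 (adjusted p = 1 each).

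The immediate early list was higher with AC170222 (0 of 23 called, 2 over the list alone; median 0.31, adjusted p = 0.0257, 0.405 with an estimated correlation). Nuclear-retained RNA was lower with AC3174 (median -0.55, adjusted p = 0.000129), AC170222 (-0.48, 0.00913) and the combination (-0.52, 0.00573), with Neat1 at -0.52 ± 0.18, -0.45 ± 0.18 and -0.44 ± 0.18; with an estimated correlation the list had an adjusted p of 0.894, 0.726 and 0.775. Endothelial genes were lower with the combination (0 of 10 called; median -2.34, adjusted p = 0.000392, 0.0625 with an estimated correlation) and with AC170222 (-0.74, 0.0279), as for Itm2a (-1.36 ± 0.57 and -1.20 ± 0.57). Genes of the cerebellar list, not all of them specific to that tissue, were higher with the combination (0 of 6 called, 1 over the list alone, median 2.61, adjusted p = 0.0122, 0.775 with an estimated correlation), with Car8 at 2.12 ± 0.81. Of 17477 genes edgeR called 0 for each drug (841, 731 and 940 at an unadjusted p under 0.05; 229, 217 and 269 by DESeq2, 0, 0 and 0 by limma-voom); without AC3174 2 or combination 2 it called 1 for the drug concerned. With an estimated correlation the lowest adjusted p of the lists was 0.894, 0.405 and 0.0625. With AC170222 the endothelial list lost its call without AC170222 1, 2 or 3 or saline 3 (adjusted p up to 0.137), immediate early without AC170222 1 or 3 or saline 1 (up to 0.108) and nuclear-retained without AC170222 2 or saline 1 (up to 0.261). With the combination the cerebellar list lost its call without combination 2 (adjusted p of 0.588) and nuclear-retained without combination 1 or saline 1 (up to 0.242).

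None of the smaller list differences in the DVC input was called at an estimated correlation (lowest adjusted p = 0.894 with AC3174 and 0.405 with AC170222). They stood in ribosomal protein mRNA with AC3174 (median -0.19, adjusted p = 1.95e-06) and AC170222 (-0.11, 0.0279), mitochondrially encoded mRNA with AC3174 (0.84, 0.00735) and AC170222 (-0.40, 0.0359). With AC170222 they also stood in respiratory chain mRNA (-0.11, 0.031), unfolded protein response genes (-0.25, 0.0257) and DVC neuron markers (0.25, 0.0375). The ribosomal protein difference with AC3174 turned in direction with the library set as a covariate (adjusted p = 3e-06). Besides Ccn1, the smallest p values belonged to Jsrp1 (0 with AC3174, at least 137-fold lower) and Fam167a (0 with saline, at least 112-fold, 105-fold and 131-fold higher with the drugs). Others were Hmgcll1 (-1.68 ± 0.29) with AC170222 and Alox12b with the combination (0, at least 223-fold lower, adjusted p = 0.273). With AC3174 the ribosomal protein list lost its call without AC3174 3 (adjusted p of 0.609) and mitochondrially encoded without AC3174 1 or saline 3 (up to 0.434). With AC170222 the ribosomal protein list lost its call without AC170222 2 or 3 or saline 1 or 2 (adjusted p up to 0.739), DVC neuron without AC170222 1, 2 or 3 or saline 1 or 3 (up to 0.909), mitochondrially encoded without AC170222 2 or 3 or saline 1 or 2 (up to 0.525), respiratory chain without AC170222 2 or 3 or saline 2 or 3 (up to 0.492) and unfolded protein response without AC170222 3 or saline 1 (up to 0.399).

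In MBH, again no gene passed the test in the IP libraries. Fos was at 104 ± 61.3 CPM with saline, 61.4 ± 56.8 with AC3174, 39.5 ± 42.0 with AC170222 and 94.6 ± 46.8 with the combination. Its log2 differences from saline were -0.73, -1.38 and -0.12. Cckar stood at 0.0154 to 7.34 CPM over the 4 treatments and Cckbr at 0 to 3.92 (adjusted p = 1 each), and Glp1r, at 0 to 2.23 CPM, had too few counts to be tested. Tle2 was at 25.0 ± 7.60 CPM with saline, 31.4 ± 4.32 with the combination and 0 in the 3 AC3174 libraries. This is at least 1110-fold and 1400-fold lower. AC3174 1, 2 and 3 lacked 0.55%, 17.3% and 50.2% of common input genes, so AC3174 zeros may be transcript loss and such folds no bounds. With AC170222 Efhd2 was at 59.5 ± 18.4 against 301 ± 182 CPM with saline (log2 -2.35 ± 0.65) and 308 ± 72.7 with the combination (2.43 ± 0.65). Slc7a11 had a log2 of 10.26 ± 2.39. Etnk1 (1.98 ± 0.50) was among the smallest p for the combination versus AC170222, and Guf1 (0 with AC3174, at least 1110-fold) for the combination versus AC3174. In the non-additivity contrast Tle2 had a fitted log2 of 14.49 ± 3.23 and Lmnb1 of 20.82 ± 4.70. Each of these genes had an adjusted p of 1.

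Of 14766 genes in the MBH IP, edgeR called 0 for AC3174, AC170222 and the combination versus saline (293, 231 and 127 at an unadjusted p under 0.05; 368, 290 and 158 by DESeq2; 0, 0 and 10 by limma-voom). It also called 0 for the combination versus AC3174 (309; 344 and 0), versus AC170222 (233; 281 and 0) and for non-additivity (377; 487 and 0). Without AC3174 1 it called 1 for AC3174 versus saline and 2 for the combination versus AC3174. With the combination, ribosomal protein mRNA (median -0.46, adjusted p = 1.86e-10), mitochondrially encoded mRNA (-3.05, 6.92e-08), microglial genes (-1.72, 0.00464), respiratory chain mRNA (-0.18, 0.00591) and nuclear-retained RNA (-1.54, 0.0333) were lower than with saline. At an estimated correlation no list was called in any of these 6 comparisons (lowest adjusted p = 0.734). Interferon response genes were higher with AC170222 (0.85, 0.0397, 0.912 with an estimated correlation), with Bst2 at 8.09 ± 14 CPM and 2 of 3 libraries at 0. No list was called with AC3174 (lowest adjusted p = 0.101). With a block on the sample number edgeR called 0 genes in each of these 6 comparisons. With AC170222 the interferon response list lost its call without AC170222 1, 2 or 3 or saline 1 or 3 (adjusted p up to 0.777). With the combination the respiratory chain list lost its call without combination 1 or saline 3 (adjusted p up to 0.991) and nuclear-retained without combination 2 or 3 or saline 3 (up to 0.541).

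The combination had lower ribosomal protein mRNA than AC3174 in the MBH IP (median -0.20, adjusted p = 3.21e-07), where again no list was called at an estimated correlation. Against AC170222 it had lower ribosomal protein (-0.48, 2.06e-13), mitochondrially encoded (-2.58, 0.00202), respiratory chain (-0.19, 0.000257), nuclear-retained (-2.64, 0.0308), meningeal (-1.45, 0.0338) and interferon response RNA (-1.45, 0.0338) and higher oligodendrocyte precursor RNA (3.07, 0.0182). With a block on the sample number the meningeal and interferon response lists were no longer called (adjusted p = 0.0557 and 0.084). In the non-additivity contrast, where the median of all genes was 0.46, interferon response (-0.73, 0.0136, 0.972 with an estimated correlation) and ribosomal protein genes (-0.14, 1.48e-06) were lower. Respiratory chain genes lay below the other genes there, though not below 0 (median 0.12, adjusted p = 0.0235). Without the low-complexity libraries the ribosomal protein difference from AC3174 and both ribosomal protein and respiratory chain in the non-additivity contrast turned in direction (adjusted p = 1.5e-05, 5e-06 and 1.4e-05). Against AC3174 the ribosomal protein list lost its call without AC3174 3 or combination 1 (adjusted p up to 0.391). Against AC170222 the interferon response list lost its call without AC170222 1, 2 or 3 or combination 1 or 3 (adjusted p up to 0.254), meningeal without AC170222 1 or 3 or combination 2 or 3 (up to 0.419), mitochondrially encoded without AC170222 3 or combination 2 (up to 0.785), respiratory chain without AC170222 2 or combination 1 (up to 0.432), nuclear-retained without AC170222 1 or 3 or combination 2 or 3 (up to 0.988) and oligodendrocyte precursor without AC170222 1, 2 or 3 (up to 0.0948). For non-additivity the ribosomal protein list lost its call without AC3174 3 or combination 1 (adjusted p up to 0.0787), interferon response without AC170222 2, AC3174 2 or 3, combination 1 or saline 1 or 3 (up to 0.264) and respiratory chain without AC170222 2, AC3174 2 or 3, combination 1 or saline 1 or 2 (up to 0.692).

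In the MBH ratio edgeR called 0 of 17461 genes for each drug (959, 922 and 700 at an unadjusted p under 0.05; 1051, 955 and 669 by DESeq2; 0, 0 and 22 by limma-voom). Without AC3174 1 it called 488 for that drug, and without AC170222 1 it called 20. Tle2 had a fitted log2 of -13.36 ± 2.51 with AC3174 (adjusted p = 0.801), Efhd2 -4.19 ± 0.86 and Uri1 -4.40 ± 0.92 with AC170222 (0.839). Entpd1, at 9.59 ± 8.22 CPM in the IP with the combination and 0 with saline, had an adjusted p of 1. Respiratory chain mRNA had a higher ratio with AC3174 (median 0.12, adjusted p = 0.0179), AC170222 (0.40, 1.91e-05) and the combination (0.38, 0.000877). For the MBH ratio no list was called at an estimated correlation (lowest adjusted p = 0.887, 0.949 and 0.861). Ribosomal protein mRNA had a higher one with AC170222 (0.27, 2.04e-05). With AC3174 it was called against a median of -0.40 over all genes while its own median was 0.03 (adjusted p = 0.027), and without the low-complexity libraries the direction turned (adjusted p = 0.00527). Lower was the ratio of mitochondrially encoded mRNA with AC3174 (-2.71, 0.0451). With the combination microglial (-2.09, 0.026), endothelial (-2.53, -2.34 with bounds, 0.0389) and mitochondrially encoded genes (-2.05, 0.0332) had a lower ratio, and these 3 were not called with the sample as a block (adjusted p = 0.0879, 0.107 and 0.0879). For AC3174 the ribosomal protein list lost its call without AC3174 2 or 3 or saline 1 or 2 (adjusted p up to 0.877), mitochondrially encoded without AC3174 1 or 2 or saline 1 or 3 (up to 0.929) and respiratory chain without AC3174 2 or 3 or saline 2 (up to 0.945). For AC170222 the ribosomal protein list lost its call without AC170222 2 or 3 or saline 2 (adjusted p up to 0.806) and respiratory chain without AC170222 2 or saline 2 (up to 0.295). For the combination the endothelial list lost its call without combination 1, 2 or 3 or saline 1 or 3 (adjusted p up to 0.398), microglial without combination 2 or 3 or saline 2 or 3 (up to 0.389), mitochondrially encoded without combination 2 or saline 1 or 3 (up to 0.589) and respiratory chain without combination 2 or saline 2 (up to 0.666).

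In the MBH input, Fos was at 31.2 ± 10.4 CPM with saline, and 0 of the 9 drug inputs lay above the highest saline input. Cckar had log2 differences of 3.39, 4.17 and 3.66 (adjusted p = 0.637, 0.71 and 0.657), Cckbr of 1.41, 0.91 and 0.31 (0.944, 0.996 and 1) and Glp1r of -0.61, -1.60 and -2.08 (0.994, 0.996 and 0.967). Ribosomal protein mRNA was lower with AC3174 (median -0.36, adjusted p = 5.39e-10), AC170222 (-0.30, 3.67e-09) and the combination (-0.67, 6.38e-30). At an estimated correlation no list was called in the MBH input (lowest adjusted p = 0.683, 0.779 and 0.454). The saline inputs differed among themselves, with a median log2 of these genes against the saline mean of 0.02, 0.28 and -0.43 in saline 1, 2 and 3. Respiratory chain mRNA was lower as well (-0.45, 2.14e-10; -0.42, 4.34e-11; -0.62, 4.47e-20), with Ndufa10 at -0.75 ± 0.21, -0.56 ± 0.21 and -0.68 ± 0.21. Hypothalamic transcription factors were higher with AC3174 (0 of 13 called, 1 over the list alone; median 1.16, adjusted p = 0.00111, 0.137 with the library set as a covariate), with Nkx2-1 at 2.75 ± 0.58. With that covariate the ribosomal protein and respiratory chain differences with AC3174 were no longer called (adjusted p = 0.515 and 0.981). With the combination, red blood cell genes (median -1.96, adjusted p = 0.0063), arcuate neuropeptide genes (-0.43, 0.0152) and mitochondrially encoded mRNA (-0.74, 0.0152) were lower, with Sst at -0.75 ± 0.23. The last of these turned in direction with the library set as a covariate (adjusted p = 1.8e-05). Of 16622 genes edgeR called 0 for each drug (1427, 1092 and 1424 at an unadjusted p under 0.05; 740, 573 and 571 by DESeq2; 0, 0 and 0 by limma-voom), and without saline 3 it called 7, 6 and 7. Zfp41, at 0 in the saline inputs, was among the smallest p with each drug (at least 1570-fold, 718-fold and 930-fold higher, adjusted p = 0.348, 0.502 and 0.388). For AC170222 the ribosomal protein list lost its call without saline 2 (adjusted p of 0.0845). For the combination the arcuate neuropeptide list lost its call without combination 2 or saline 1 or 3 (adjusted p up to 0.156), mitochondrially encoded without combination 2 or 3 or saline 1 or 2 (up to 0.443) and red blood cell without saline 1 (0.0956).

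Regional identity was read from the saline inputs. Hindbrain Hox genes were higher in DVC. Hoxb5 was at 138 ± 47.8 CPM against 0 in all 3 MBH libraries, at least 9300-fold (SD, n = 3; adjusted p = 0.0318 by edgeR), Hoxa5 at least 5680-fold (0.0419) and Hoxc4 at least 3760-fold (0.0429). The glycine transporter gene Slc6a5 (75.5 ± 20.2 against 0.00459 ± 0.00795 CPM), the neurofilament gene Nefm (1340 ± 450 against 169 ± 15.4 CPM), Pcp4l1 (log2 2.88 ± 0.22), Sparcl1 (2.71 ± 0.21), Cplx1 (2.50 ± 0.20) and Nacc2 (2.22 ± 0.24) were also higher in DVC. Higher in MBH were Fezf1 (at least 4920-fold) and Dlx1 (at least 4900-fold), which pattern the forebrain, and Six6 (44.6 ± 13.8 against 0.00414 ± 0.00717 CPM in DVC), Ppp1r17 (56.9 ± 18.2 against 0.00392 ± 0.00679 CPM). Further genes were the calcium buffer gene Calb1 (1080 ± 136 against 108 ± 19.9 CPM in DVC), Nrgn (176 ± 5.29 against 14.5 ± 2.56 CPM), Gstm6 (log2 -3.94 ± 0.40), Asb4 (-3.78 ± 0.39) and Camkv (-2.81 ± 0.28). Hoxb5 lies on chromosome 11 from 96303336 to 96306121 and Calb1 on chromosome 4 from 15881264 to 15908064.

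Of 15276 genes edgeR called 10 higher and 9 lower in DVC, with 1971 at an unadjusted p under 0.05, and 18 met the naming rule. The Hox list was higher (3 of 12 called, 12 over the list alone; median 12.20, 9.97 with bounds; adjusted p = 3.49e-30, 0.0509 with an estimated correlation). Hypothalamic transcription factors were lower (2 of 10 called, 5 over the list alone; median -6.36, -5.79 with bounds; adjusted p = 7.16e-11, 0.18 with an estimated correlation). Oligodendrocyte genes were higher in DVC (0 of 12 called, 8 over the list alone; median 1.72, adjusted p = 5.5e-11). This list and the 6 that follow were not called at an estimated correlation (adjusted p = 0.128 to 0.233). Higher were also astrocyte genes (0 of 12, 5 over the list alone; 1.30, 2.23e-05), cholinergic motor genes (0 of 7, 6 over the list alone; 6.27, 0.000107) and DVC neuron markers (0 of 8, 3 over the list alone; 3.09, 0.000135). Arcuate neuropeptide genes were lower in DVC (0 of 11, 2 over the list alone; -2, 1.35e-05), with Pomc at 3.70 ± 1.15 against 75.5 ± 12.7 CPM. So were other hypothalamic neuropeptide genes (6 over the list alone; -0.84, 1.65e-05) such as Hdc (-5.36 ± 0.60), and ribosomal protein mRNA (45 of 78 over the list alone; -0.83, 2.03e-25). Fos (-0.67 ± 0.53, adjusted p = 0.73), Cckar (3.93 ± 3.20, 0.739) and Cckbr (0.41 ± 1.96, 0.968) did not pass the test. Without MBH saline 2 the count was 164, and without any other of the 6 libraries 0. With a block on the sample number it was 0.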

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

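The test of DVC against MBH was planned. No group of 3 was tested for a sample far from the others, and no explanation was tested for values in this part. The edgeR fit of 19416 genes over 48 libraries had no block. In it, 852 genes differed between regions in IP versus input (453 higher in DVC, 399 lower). Region is partly confounded with low complexity (5 of 6 libraries in MBH). In IP, 7 genes differed in the change with AC3174, 5 with AC170222 and 0 with the combination (1641 at an unadjusted p under 0.05). No other tool or setting was run.

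Respiratory chain and ribosomal protein mRNA had the lowest adjusted p among the lists compared between the regions. The IP-versus-input log2 difference was higher in DVC by a median of 1.03 for nuclear-encoded respiratory chain genes (42 of 72 members differed, 71 positive; adjusted p = 8.27e-39, 0.066 with an estimated correlation). It was higher by a median of 1.01 for ribosomal protein genes (34 of 80 differed, 78 positive; adjusted p = 1.54e-37, 0.199 with an estimated correlation). It was also higher for neuronal markers (median 0.65, adjusted p = 0.00521) and heat shock genes (0.62, 0.0405). Lower in DVC than in MBH were microglial (-3.11, 0.0187), oligodendrocyte precursor (-4.17, 0.0187), oligodendrocyte (-0.58, 0.0405) and immediate early genes (-0.86, 0.0405). By the estimated correlation these 6 lists had an adjusted p of 0.31 to 0.679. In the IP drug contrasts, the change with AC170222 was lower in DVC than in MBH for ribosomal protein (-0.40, 1.33e-08; 10 of 80 positive) and respiratory chain genes (-0.34, 1.05e-06; 17 of 72 positive) and higher for immediate early genes (0.80, 0.0317; 14 of 24 positive). With AC3174 it was lower for ribosomal protein genes (-0.29, 0.0018; 23 of 80 positive). With an estimated correlation the adjusted p of these lists was 0.956 (AC170222) and 0.994 (AC3174).

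Among the genes named for IP versus input, Atp5mpl (1.56 ± 0.29) and Pcp4l1 (1.14 ± 0.30) had a higher log2 difference in DVC, and Ficd a higher fitted one (8.61 ± 2.00). Lower in DVC than in MBH were Srrm2 (-1.49 ± 0.43), Map7d2 (-1.74 ± 0.41) and Bcas1 (-1.82 ± 0.42). Lower fitted values, with 7 to 11 of 12 DVC IP libraries at 0, were those of Kcna3 (fitted -7.80 ± 1.72), P2ry12 (-7.57 ± 2.12), Tmem158 (-9.76 ± 1.68), Prrt3 (-8.66 ± 2.03), Fam171a2 (-8.63 ± 1.65), Il13ra1 (-10.19 ± 2.05) and Zfp773 (-10.42 ± 2.33). In the IP drug contrasts, Nr4a1 differed between the regions with AC3174 (fitted 13.86 ± 2.47, adjusted p = 0.0136) and AC170222 (13.98 ± 2.48, adjusted p = 0.0371). Gadd45b also differed with AC3174 (13.90 ± 2.20, adjusted p = 0.00645). It had 0 counts in the 3 MBH IP libraries of AC3174, of which replicates 2 and 3 are of low complexity. The other genes that differ with AC3174 are Pan2, Map4k5, Cyb5d2, Rfx7 and St3gal6, and with AC170222 Map4k5, Paqr9, Scaf4 and Rfx7 (fitted log2 differences of 13.85 to 24.91, adjusted p of 0.0136 to 0.0492); they were named after their values were seen.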

How the results depend on the processing

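The deposited counts carry no molecular identifiers, and many transcripts counted in the inputs had no count in the IP. Leaving out the 6 low-complexity libraries, limma-voom and the minimum of 10 CPM were chosen after seeing the data, and genes are named beside counts of 5 or fewer after their values were seen; for each change below the cause was not tested unless stated.

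With DESeq2, every count of genes moved upward: IP versus input gave 6091 in DVC and 1846 in MBH, the DVC ratios 1919, 1649 and 1800 (AC3174, AC170222, combination) and the MBH ratios 1051, 955 and 669. DVC IP drug contrasts gave 1144, 906 and 935, combination versus AC3174, AC170222 and non-additivity 442, 387 and 883, and the same contrasts in MBH IP 368, 290, 158, 344, 281 and 487. DVC inputs gave 229, 217 and 269, MBH inputs 740, 573 and 571, and the saline regions 1239. With limma-voom IP versus input gave 7000 and 617, the DVC ratios 0 (AC3174) and 4 (combination: Tmem176b, Atg4a, Slc25a24, Lrp8os3). DVC IP drug contrasts gave 3 (Mlh3, Kcnj11, Nr4a1), 35 and 31, combination versus AC170222 35, non-additivity 5 (Acta2, Mlh3, Nr4a1, Mapkapk3, Paqr9). To these come the MBH combination ratio 22, MBH IP combination 10 and the saline regions 450. The library set covariate gave 3 (Nr4a1, Mlh3, Rfx7) and 4 (the same and Hgh1) for the DVC ratios of AC170222 and the combination, 48 for MBH IP versus input, and 3 (Usp8, Dpp9, Cdkn2aipnl), 1 and 1 (Usp8) in MBH IP for AC3174, the combination and combination versus AC170222. Without a low-count filter the AC170222 ratio in DVC gave 3 (Nr4a1, Mlh3, Rfx7) and MBH IP versus input 44. With a mean of at least 10 CPM, where fewer genes were tested, IP versus input gave 2098 and 51, the AC3174 ratio 12 and the saline regions 44. With the sample shared by input and IP as a block, fewer residual degrees of freedom remained, and IP versus input gave 1401 and 3 (Srrm2, Fth1 and Calm2) and the 3 DVC ratios 0, 0 and 0. With a block on the sample number the saline regions gave 0. Without the low-complexity libraries MBH IP versus input gave 363, the DVC ratios 74, 61 and 74, DVC IP combination versus saline 2 (Fam135a, Mlh3) and the MBH AC3174 ratio 1 (Nupl2). DESeq2 size factors within edgeR kept every count within 1.5 times.

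Without 1 sample at a time, IP versus input gave 2759 to 4213 genes in DVC and 4 to 587 in MBH (587 without AC3174 1, 4 without combination 2 or combination 3, over 1.5 times from 79 without any sample but AC3174 3 and AC170222 1). The DVC ratios gave 6 to 50 for AC3174, 2 to 38 for AC170222 and 3 to 42 for the combination, each moved over 1.5 times without any of its 6 samples apart from AC3174 2. The MBH ratios gave 0 to 488 (without AC3174 1), 0 to 20 (without AC170222 1) and 0 to 0. In DVC IP, AC3174 gave 0 to 1 (without saline 1) and the other 5 contrasts 0 to 0; in DVC inputs, AC3174 gave 0 to 1 (without AC3174 2), AC170222 0 to 0 and the combination 0 to 1 (without combination 2). In MBH IP, AC3174 gave 0 to 1 and combination versus AC3174 0 to 2 (both without AC3174 1), the other 4 contrasts 0 to 0. MBH inputs gave 0 to 7, 0 to 6 and 0 to 7 (without saline 3; 1 for the combination without combination 2), and the saline regions 0 to 164 (164 without MBH saline 2, 0 without any other).

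Of 117 gene list calls, 0 were called with an estimated correlation, the lowest adjusted p being 0.0509. Among them 104 of 117 remained with the replicate block, 84 of 98 with the library set and 45 of 74 without the low-complexity libraries, where 70 lists were called in all, including lists not called with them. Without each sample in turn, a test chosen after seeing the data, 44 of 117 calls were kept throughout, 73 ended without at least 1 sample and 0 reversed. The direction reversed for ribosomal protein mRNA with the library set in DVC input with AC3174 (adjusted p = 2.55e-06), for mitochondrially encoded mRNA with the set in MBH input with the combination (1.8e-05). Without the low-complexity libraries it reversed for ribosomal protein mRNA in the MBH AC3174 ratio (0.00527), MBH IP combination versus AC3174 (1.5e-05) and MBH non-additivity (5.45e-06) and for respiratory chain mRNA in MBH non-additivity (1.4e-05). Of the values of 137 gene results called by edgeR, 1944 under the alternatives kept their direction and their side of the threshold, 505 lost the call and 0 reversed. Of 297 not called, 201 values passed the threshold under an alternative and 3939 did not.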

Other observations

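The tests of a drug response of immediate early genes, of random loss at the rate of each library and of nuclear-retained RNA were chosen only after the result was seen, and the tests on trios of libraries at 0, on DESeq2 and counts of 0 and on other groupings of the samples were written before their results.

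Some gene groups not described above differed between the saline inputs of the regions. Endothelial genes (median log2 2.39, adjusted p = 0.00899), cholesterol synthesis genes (0.94, 0.0055), nuclear-retained RNA (1.34, 0.00254), glucocorticoid response genes (0.45, 0.0218), meningeal fibroblast genes (1.21, 0.0395), glutamatergic (0.92, 0.0487) and inhibitory neuron genes (1.11, 0.0283) and neuronal markers (0.38, 0.00167) were higher in DVC. Respiratory chain mRNA (-0.30, 0.000653) and cerebellar genes (-0.17, 0.00268) were lower in DVC, the latter with Calb1 and Ppp1r17 called lower and 3 of 6 members higher. At the estimated correlation none of these 10 lists was called. With a block on the sample number the cerebellar, glutamatergic and inhibitory neuron lists were not called (adjusted p = 0.184, 0.0563 and 0.186). The cerebellar list lost its call without MBH saline 3 (adjusted p of 0.0529), glucocorticoid response without MBH saline 1 or 3 (up to 0.295), glutamatergic without DVC saline 3 or MBH saline 3 (up to 0.14), inhibitory neuron without DVC saline 1, 2 or 3 or MBH saline 1 or 3 (up to 0.147), meningeal without MBH saline 1 or 3 (up to 0.106), respiratory chain without MBH saline 2 (0.535) and nuclear-retained without MBH saline 3 (0.0898). Gcg was counted in DVC and had 0 counts in the 24 MBH libraries. In the saline inputs the oxytocin gene Oxt had 0 counts in the 3 DVC libraries, while Slc5a7 had 0 counts in the 3 MBH libraries. Glp1r reached at most 3.44 ± 3.06 CPM in any of the 16 groups (MBH input, saline). In DVC inputs Cckar ranged from 1.85 ± 1.63 (AC170222) to 8.55 ± 1.53 CPM (AC3174) and Cckbr from 4.75 ± 0.832 (AC3174) to 8.11 ± 2.01 CPM (combination).

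Nr4a1, Mlh3, Rfx7, Hgh1 and Lrp8os3 had a higher IP-to-input ratio with each drug in DVC, because the saline IP libraries held next to none of their transcripts. Random loss of transcripts may be the source and stays open: of 9753 genes common in DVC inputs, 21 were at 0 in the 3 saline libraries and counted in 8 or 9 of the rest, against a median of 17 (5 to 33) in 5000 permutations that kept the zeros of each gene and library (0.18 had as many). Of 11940 genes with at least 4 CPM in the IP, 41 were so, against a median of 31 (13 to 51; 0.043 had as many). Of 45 trios with saline 3 but without AC3174 3, the library with most zeros, only the saline trio had 41. The next had 31 (permuted median 26). A response of activity-induced genes to the drugs stays open as a hypothesis, since Nr4a1 is in the immediate early list but the list was not called in any of the 3 ratio comparisons (lowest adjusted p = 0.0768), and the other 4 genes are not in it. Each call ended with the sample as a block (Nr4a1 with AC3174: fitted log2 14.45 ± 1.97, adjusted p = 0.677, against 14.24 ± 1.51). The ratio fit pooled IP with less variable inputs, and IP alone gave 13.71 ± 1.94 (not called).

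DESeq2 called 1144, 906 and 935 genes for AC3174, AC170222 and the combination versus saline in DVC IP, where edgeR called 0 (1041, 830 and 861 at an unadjusted p under 0.05). Libraries with counts of 0 may be the source: groupings that mix drug and saline libraries gave a median of 1033, 710 and 692 genes by DESeq2 (highest 1737, 888 and 841). Of the genes called, 82.9%, 92.5% and 90.6% had a library at 0, against 52.8%, 40.8% and 41.1% of the genes tested. A part of the calls with AC170222 and the combination, whose counts lay above all 9 other groupings, stays open as a response to the drug, and 10 groupings are too few for a share under 0.05.

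Depletion of nuclear-retained RNA from the IP varied widely between samples. The library set may be a cause: it held 55.5% of the sum of squares in DVC (permutation p = 0.04, adjusted 0.08) and 58.1% in MBH (0.014, adjusted 0.042, over 6 tests). The sample number, which overlaps with the set, may be a cause as well, with 44.6% in DVC (permutation p = 0.08, adjusted 0.12) and 60.9% in MBH (0.01, adjusted 0.042), and these data do not separate the 2. Treatment held 12.1% (permutation p = 0.75) and 12.5% (0.78), less than the median of 22.5% and 23.7% under permuted labels, but 12 samples leave a drug effect open. Set is partly confounded with treatment and in doubt for MBH combination 1 and 2. The labels do not define the number, and all 3 causes stay open.

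Other groupings of the same samples gave these counts by edgeR. For IP versus input the real labels gave more genes than any of the 29 other groupings that exchange input and IP within samples, in DVC (3776 against at most 1311; 1 of 30 as large) and in MBH (79 against at most 1; 1 of 30). Chance is unlikely for both, but the MBH count moved with single samples. The non-additivity counts of 0 were reached by all 100 groupings in each region, as any count reaches 0. The highest other counts, 16 in DVC and 261 in MBH, point to a sample structure whose cause was not tested. Each comparison of 3 with 3 samples has 10 groupings, too few for a share under 0.05. The saline regions gave 19 against at most 0 (1 of 10 as large). The DVC ratios gave 7 against at most 241 for AC3174 (9 of 10 as large), 5 against 5 for AC170222 (2 of 10) and 7 against 8 for the combination (2 of 10). The grouping with 241 genes set saline 3 and AC3174 3, the IP libraries with the fewest genes, on the same side. The other comparisons gave 0 in 10 of 10 groupings as large, with a highest other count of 34 for AC3174 and 0 for the rest in DVC IP, 14 for AC3174 and 0 for the rest in MBH IP. The highest others were 0, 0 and 2 in DVC inputs, 1, 3 and 0 in MBH inputs and 431, 24 and 0 in the MBH ratios.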
